A study of Caenorhabditis elegans with 21 samples.

How the data were processed

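Gene expression was measured in single Caenorhabditis elegans embryos on 2-colour Agilent oligonucleotide arrays. Per the labels, 2-cell embryos were taken from wild-type mothers (strain N2) or mes-2 mutant mothers (strain SS186) and kept at 20 °C until their gut founder cell E had given rise to 2, 4 or 8 cells, the stages called 2E (75 min), 4E (120 min) and 8E (3 h). MES-2 is the Enhancer of zeste homologue of the worm and the catalytic part of its Polycomb repressive complex. Each array held the amplified cDNA of 1 embryo in Cy5 and a mix of wild-type embryos in Cy3, with no dye swap, so the direction of every ratio comes from the dyes in the labels and a dye effect is shared by all arrays. There were 21 arrays in 7 groups of 3: wild type at the 2-cell, 2E, 4E and 8E stages and mes-2 at 2E, 4E and 8E. The series design calls the replicates biological; beyond their being single embryos the labels do not say how they came about, and the number of arrays limits the precision of every value. Per the labels' protocols, cDNA was poly(A)-tailed, amplified by many cycles of PCR and reamplified where needed, so the signal of a rare transcript can carry amplification noise. The labelling protocol in the labels speaks of immunoprecipitated DNA, while the sample type and the extraction describe embryo cDNA, which is how the arrays were read here.

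The deposited scanner files give the mean pixel intensity and the local background intensity of each spot in both channels, on a linear scale and without normalization, per the file headers. They also give background-subtracted, dye-normalized intensities and, as a log10 ratio of Cy5 over Cy3, the scanner software's own result, per the file headers. The headers name Agilent Feature Extraction 8.5.1.1 for most arrays, 8.1.1.1 for wild-type 8E replicate 3 and 9.1.3.1 for wild-type 2-cell replicates 2 and 3, while the submitters' processing notes name version 9.5.1. The authors also deposited a table with 1 value per probe and array. Set against the scanner values, its columns followed log2 Cy5 intensity (r of 0.944 to 1.00) and each had a median of 5.92, so the deposited values are log2 Cy5 intensities with a common median. Their sorted values were the same in the replicates of a group; the steps that made them are not given in the sources used here. Wild-type 2-cell replicates 2 and 3 were on a design with 42964 gene spots and the other arrays on a design with 21482. Both designs carried 20401 gene probes, some of them spotted more than once. Of these, 18397 were matched to 1 gene name through a table of RefSeq names (assembly WBcel235, used for names and chromosomes alone), 722 to several genes, 718 kept the name in the scanner files and 564 had no gene. Probes of several genes were named by all of them, and none was used to name a single gene. The build behind the probe design is not given in the sources used here, so no coordinates are printed.

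Values were computed in R 4.3.3 with limma 3.58.1. Mean intensities were background-corrected with normexp (offset 50), ratios were normalized within each array by loess with control spots at weight 0, spots the scanner software marked as outliers were left out, and spots of a probe were averaged. A probe was kept if it was well above background in Cy5 on at least 3 arrays, which left 12903 probes on the 18 arrays from 2E to 8E. Where a gene had several probes the brightest was used. Each of 12236 genes (12554 with the 2-cell arrays) was fitted with 1 mean per group and moderated by eBayes. The 18 arrays shared a single estimate of the spread, which treats all groups as equally variable, and 2E against 2-cell in wild type used all 21. Adjusted p-values are Benjamini-Hochberg values over the genes of a comparison, and a gene was called at an adjusted p under 0.05. Standard errors are those of limma on the log2 scale, with n = 3 embryos in each group. Because Cy3 differed between arrays, every comparison was also run on Cy5 alone (quantile-normalized between arrays) and on Cy3 alone. A gene that was not well above background on any array of a group has only a bound there: the fold is then given as "at least", from the bright group's mean Cy5 level over, on each array of the dim group, the higher of the lowest level counted as well above background and the probe's own level. This bound is a ratio of Cy5 levels and can exceed the fold of the log ratio, to which the adjusted p beside it belongs. It is open to dye bias without dye swaps.

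Before the data were examined, 18 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The lists covered lineage regulators (endoderm, mesoderm and pharynx, ectoderm, Notch pathway, Hox genes), differentiation genes (gut, muscle, pharynx, epidermis, neuron), maternal oocyte transcripts, germ line and P granules, chromatin regulators of the MES and Polycomb groups, cell cycle and DNA replication, ribosomal proteins, heat shock and stress, X-linked genes, and transcripts of the mother's intestine and of sperm as markers of material that could adhere to an embryo. Some genes stand in 2 lists: nob-1 and php-3 are both Hox genes and ectoderm regulators, and mes-4 is in the germ line and the chromatin lists. Each list was tested with limma's camera against the other genes with a preset correlation of 0.01, adjusted over the 18 lists, and again with a correlation estimated from the data. Genes of a list are not independent of each other. The genes named are mes-2, the 8 largest rises and the 8 largest falls among genes that were called, whose groups did not overlap and that were well above background in a whole group, and up to 4 members of each list with the smallest p. Where fewer than 5 genes passed in a direction, the 5 smallest p-values were taken. For the difference between genotypes in the change from 2E to 8E, overlap of groups has no meaning and was not asked for. Genes with no symbol go by their sequence name.

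A stage index placed each embryo between the wild-type 2E mean (0) and the wild-type 8E mean (1), over the genes that changed between these groups. For each wild-type 2E or 8E embryo the genes and the axis were made again without its array, so these embryos need not lie at 0 and 1. The other embryos were scored as the mean over these left-out axes. Group means of the index were compared by a two-sided exact permutation test, whose smallest p with 3 against 3 embryos is 0.1. At 2E and 8E the wild-type and mes-2 embryos are scored in these different ways. The test treats their scores as exchangeable, so its p-values are only approximate there. The analysis steps were tested on simulated data built from the 12236 genes of mes-2 against wild type at 8E with 200 genes changed. There, 105 genes were called, 5 of them falsely (4.76%), and the share recovered was 19.4% at a log2 change of 1, 43.3% at 2 and 87.9% at 4. The list of 25 genes shifted in the simulation was found with 0 other lists. Embryos placed at 0.5 on the index were found at 0.494, and wild-type 8E embryos, placed at 1, at 0.949. The simulated noise was independent between genes, with 1 spread per gene for all groups and no batch or weak reference. These rates therefore check the steps and are not error rates of the real data.

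Scan days and slides were read from the scanner files as batches. The arrays were scanned on 9 days and lay on 14 slides, and wild-type and mes-2 arrays never shared a scan day. Genotype and scan day therefore cannot be told apart by a fixed term, and scan day was fitted as a random block instead. Wild-type 2E and 4E shared 2 scan days, on which their difference was also taken within the day. Alternatives were the deposited processed intensities, no background correction, median centring in place of loess, normalization between arrays, Cy5 alone, other filters on dim probes, the mean over a gene's probes, the deposited value table, blocks for replicate number, slide and scan day, array quality weights, fits of the compared arrays alone, an estimated correlation in the list tests, and leaving out each array in turn. Scale normalization between arrays, a fit without the 2 wild-type 8E arrays with a weak reference, and slide or scan day as a block in the list tests of wild-type 4E against 2E and mes-2 8E against 2E were added after the data had been seen. All arrays and all columns that hold values of a sample could be assigned.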

Results

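Single embryos of wild type and of mes-2 mutants were compared at 3 stages of early development, and wild-type embryos were followed from the 2-cell stage on. Each of the 7 groups held 3 embryos. On single arrays, 27.1% to 55.1% of probes were well above background in the embryo channel (Cy5). The wild-type reference channel (Cy3) was well above background at 40.6% to 56.9% of probes, except on wild-type 8E replicates 1 and 2, where the share was 19.4% and 24.7%. On these 2 arrays the reference followed that of the other arrays less closely (median r of 0.768 and 0.804 across probes, which are not independent, against at least 0.925 elsewhere). Their log ratios ran against those of the 2-cell embryos (r of -0.325 to -0.609), and the direction was kept because the labels state the dyes. Comparisons that involve wild-type 8E are therefore given with Cy5 alone as well, for the counts and for some of the genes named. Cy5 alone is not free of what both channels share, as its changes between the genotypes correlated across genes with those of the reference channel (r = 0.543 at 2E, 0.39 at 4E and 0.369 at 8E). Embryos of a group resembled each other least in wild-type 2E (mean r of Cy5 with the rest of the group, 0.704 to 0.784), followed by wild-type 8E (0.801 to 0.858) and 2-cell embryos (0.876 to 0.908). It was 0.923 to 0.936 in wild-type 4E and 0.897 to 0.949 in the mes-2 groups.

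The gene mes-2 itself was read first in every embryo. Its log2 ratio over the reference was -0.88, -0.69 and 0.26 in the wild-type 2-cell embryos, 0.46, -2.34 and -1.35 at 2E, -4.09, -1.09 and -1.22 at 4E, and -3.34, -2.15 and -1.79 at 8E (replicates 1 to 3). In the mutant it was -1.13, -2.31 and -3.55 at 2E, -3.39, -3.70 and -4.09 at 4E, and -1.64, -2.12 and -3.61 at 8E. The probe was well above background in Cy5 in every embryo except wild-type 8E replicate 1. The genotypes did not differ at any stage by limma (-1.25 ± 0.89 SE at 2E, adjusted p = 0.431; -1.59 ± 0.89 at 4E, 0.762; -0.03 ± 0.89 at 8E, 0.987). The labels do not say what the allele changes in the transcript, so this probe does not check the genotype labels.

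The first steps of wild-type development were seen by comparing 2E with 2-cell embryos. Transcripts that rose included sepa-1, which helps to clear P granule proteins by autophagy (25.6-fold, log2 4.68 ± 1.00 SE, adjusted p = 0.0213), the very early transcript vet-1 (24.1-fold, 4.59 ± 1.13) and sdz-28 (18.2-fold, 4.18 ± 0.97). The genes Y25C1A.6 (74.6-fold), F14B6.3 (47.2-fold), K08H2.2 (44.3-fold), ZK899.6 (24.7-fold) and F40G9.9 (18.1-fold) rose as well. Among the genes that fell were memi-3 (-4.89 ± 0.53, adjusted p = 0.000544) and memi-2 (-4.71 ± 0.53, adjusted p = 0.000635), which act in female meiosis, and oma-2 (-4.70 ± 0.70, adjusted p = 0.00256), an RNA-binding regulator of oocyte maturation. The frataxin gene frh-1 (-4.81), the tubulin cofactor gene tbca-1 (-4.78) and znf-706 (-4.72) fell alongside them. For the RNA-binding protein gene cey-2 (-5.30 ± 1.05) and the small heat shock protein gene sip-1 (-4.92 ± 0.99) the fall did not pass in Cy5 alone, at adjusted p = 0.105 and 0.0951. In all, 331 of 12554 genes were called, 169 higher and 162 lower at 2E. An unadjusted p under 0.05 was found for 2001 genes, where chance would give 627.7. The groups did not overlap for 14.2% of genes, where chance gives 10%. Cy5 alone called 561 genes (198 higher and 363 lower), of which 212 were called the same way in both. The split depended on scaling: 61 higher and 113 lower with the deposited processed signals, 23 and 34 with scale normalization, and 143 and 2942 with the deposited value table. The median over all genes lay at 0.11 here and at 0.17, 0.27 and -0.28 with processed signals, median centring and the value table. No scan day held both stages, and 97 genes were called with scan day as a random block, 130 with the single 2-cell array of the shared design and 143 with array design as a term. In a fit of these 6 arrays alone limma called none (947 at an unadjusted p under 0.05), and the count was 194 without 2-cell replicate 2 (69 higher, 125 lower), 108 without 2-cell replicate 3 (36 and 72), 964 without wild-type 2E replicate 1 and 219 without wild-type 2E replicate 2 (86 and 133).

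Between 2E and 4E in wild type, F22E5.17 was the only gene called. It was well above background in all 3 embryos at 2E and in none at 4E, and lower by log2 -2.43 ± 0.31 in the log ratio (adjusted p = 0.021) and at least 5.58-fold in Cy5. Within the 2 scan days that held both stages it differed by -2.57 and -3.03 on the log2 scale. The 5 genes nearest to passing as higher were the posterior Hox gene nob-1 (3.73 ± 0.56, adjusted p = 0.0673; 4.34 and 2.24 within scan days), the forkhead gene unc-130 (3.42 ± 0.57, 0.0694), hex-1 (1.68, not well above background at 2E), ekl-6 (1.25) and C05B5.4 (3.26). Those nearest to passing as lower were sea-1 (-1.81), T07C4.3 (-1.67), T28D6.6 (-2.50) and tat-1 (-2.54). With 1 gene called by limma, 1225 had an unadjusted p under 0.05 (611.75 by chance), and the groups did not overlap for 11.1% of genes against 10% by chance. Cy5 alone called 11 genes, 6 of them higher and 5 lower. The split was 3 higher and 1 lower with processed signals and 6 and 6 with the value table. With the preset correlation 9 lists passed, and with an estimated correlation none did (adjusted p = 0.0978 to 0.289). Ribosomal protein genes had a median of 1.80 (adjusted p = 3.5e-19, and adjusted p = 0.279 with an estimated correlation), which was 0.67 on 1 shared scan day and -0.08 on the other. The median of maternal oocyte transcripts was -1.07 (adjusted p = 7.58e-06, and adjusted p = 0.231 with an estimated correlation; -0.96 and 0.08 within scan days). It was -1.39 for germ line and P granule genes (adjusted p = 0.000379, and adjusted p = 0.158 with an estimated correlation; -1.10 and -0.55). Ectoderm regulators had 0.65 (adjusted p = 4.31e-05, and adjusted p = 0.112 with an estimated correlation; 0.05 and 0.44) and Hox genes 0.54 (adjusted p = 0.00289, and adjusted p = 0.0978 with an estimated correlation; 0.52 and 0.65). For endoderm regulators it was 0.63 (adjusted p = 0.0184, and adjusted p = 0.116 with an estimated correlation; 0.19 and 0.43). Cell cycle genes had 0.74 (adjusted p = 1.11e-05, and adjusted p = 0.158 with an estimated correlation; 0.43 and 0.20) and heat shock genes 0.73 (adjusted p = 0.0248, and adjusted p = 0.289 with an estimated correlation; 0.13 and 0.87). X-linked genes had a median of 0.01 and a mean of 0.18 (adjusted p = 0.0129, and adjusted p = 0.158 with an estimated correlation). With scan day as a block endoderm, heat shock and X-linked genes did not pass (adjusted p = 0.234, 0.227 and 0.234), and with slide as a block maternal, cell cycle, endoderm and X-linked genes did not (adjusted p = 0.0564, 0.057, 0.526 and 0.178). Chromatin regulators, which missed without a block (adjusted p = 0.103), passed with slide (median 0.47, adjusted p = 0.00692) and with scan day (0.35, adjusted p = 0.00611) as a block. With scan day as a block gut genes (-0.44, adjusted p = 0.0335) and transcripts of the mother's intestine and sperm (-0.80, adjusted p = 0.0307) also passed, against adjusted p = 0.0631 and 0.923 without it. The list tests with a block used the preset correlation alone. Medians on the 2 slides that held both stages, with 1 embryo of each, differed in sign for ribosomal (1.46 and -0.61), cell cycle (0.76 and -0.17), heat shock (2.18 and -0.03), endoderm (-0.04 and 0.49), chromatin (0.66 and -0.01) and mother's intestine and sperm genes (1.34 and -2.27). They were -0.44 and -0.11 for maternal transcripts, -0.81 and -0.48 for germ line genes, 0.93 and 0.09 for ectoderm regulators and 0.82 and 0.27 for Hox genes. The shared scan days and slides hold no 2E replicate 1. In Cy5 it lay at 0.149 between 2-cell (0) and 4E (1), against 0.704 and 0.891 for replicates 2 and 3. With slide or scan day as a block the median was -0.38 or -0.32 for maternal transcripts and 0.38 or 0.33 for ribosomal protein genes. Over all genes no list member was called. Adjusted over the list alone, 4 maternal and 2 germ line genes fell and 2 ectoderm regulators, 1 Hox gene and 1 neuron gene rose. Without a block the other 9 lists did not pass, and for mesoderm and pharynx regulators, pharynx and neuron genes the median was below 0 and the mean above. The count of 1 gene became 8 without wild-type 2E replicate 2, 672 without 2E replicate 3, 2 without 4E replicate 1, 3 without 4E replicate 3 and 0 without 4E replicate 2 (898 unadjusted). F22E5.17 came to adjusted p = 0.0688 without 4E replicate 1 and 0.0958 without 4E replicate 2, and the 1 gene called with slide as a block was another. It was 0 in a fit of these arrays alone (627 unadjusted), with median centring (796) and with scale normalization (1342).

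From 4E to 8E wild-type embryos changed many genes. The secreted epidermal protein gene sym-1 rose most (640-fold, log2 9.32 ± 0.99, adjusted p = 0.000176; 5.77 in Cy5 alone), followed by the acyl-CoA dehydrogenase gene acdh-1 (206-fold, 7.69 ± 0.88), the fatty acid synthase gene fasn-1 (125-fold, 6.97 ± 0.63), zip-7 (6.53 ± 0.97), the neurotrophic factor gene manf-1 (6.23 ± 0.83) and txdc-12.1 (5.94 ± 0.95). The laminin gene epi-1 (6.08 ± 1.22) and the endoplasmic chaperone gene hsp-3 (5.69 ± 0.86) also rose, with Cy5 alone at 1.91 (adjusted p = 0.228) and 1.49 (adjusted p = 0.0646). F15B10.3 fell by 6.86 ± 1.09 on the log2 scale (adjusted p = 0.00185). Other falls were lsy-27 (-5.72), mtq-2 (-5.69), F27C1.4 (-5.55), smim-14 (-5.36), phf-10 (-5.02), bca-1 (-4.99) and snx-17 (-4.96; adjusted p = 0.108 in Cy5 alone). A total of 1022 genes were called, 603 higher and 419 lower at 8E. An unadjusted p under 0.05 was found for 2600 genes, and the groups did not overlap for 28.7% of genes against 10% by chance. The reference channel carried over 50% of the log ratio for 21.9% of the called genes. Cy5 alone called 1213 genes (671 higher, 542 lower), 610 of them in both, and without the 2 arrays of weak reference 541 were called (384 higher, 157 lower). Epidermis differentiation genes rose as a list (median 0.59, adjusted p = 0.0066, and adjusted p = 0.27 with an estimated correlation), with 5 of 27 members higher and 1 lower, or 12 and 2 adjusted over the list alone. Ribosomal protein genes lay higher in the log ratio (median 1.79, adjusted p = 2.67e-07, and adjusted p = 0.731 with an estimated correlation) but lower in Cy5 alone (-0.48, adjusted p = 0.154), so their direction is not settled; 2 members rose over all genes and none over the list alone. Gut genes passed in Cy5 alone (median 0.72, adjusted p = 0.0368, and adjusted p = 0.395 with an estimated correlation) and not in the log ratio (0.18, adjusted p = 0.254). No other list passed in either. Over all genes and over the list alone, 3 and 5 of 23 ectoderm regulators, 1 and 2 of 6 Hox genes, 2 and 3 of 17 gut genes and 7 and 7 of 39 cell cycle genes rose, and 3 and 5 cell cycle genes fell. For ectoderm regulators, cell cycle and X-linked genes the median was below 0 and the mean above, and the reverse held for pharynx genes and maternal transcripts. The split became 995 higher and 256 lower with median centring, which put the median of all genes at 0.18. No scan day held both stages, and 305 genes were called with scan day as a random block. The count was 239 in a fit of these arrays alone, 635 without 4E replicate 2 and 427 without 4E replicate 3.

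Across the whole span from 2E to 8E in wild type, several regulators of the embryo's body plan rose. The posterior Hox gene nob-1 rose 40.4-fold (log2 5.34 ± 0.56, adjusted p = 7.03e-05), the midbody Hox gene lin-39 4.59-fold in the log ratio (adjusted p = 0.00217) and at least 10.9-fold in Cy5, and the anterior Hox gene ceh-13 5.5-fold (2.46 ± 0.58, adjusted p = 0.0119). All 6 Hox genes lay above 0 and 3 were called, also over the list alone. The list passed (median 1.40, adjusted p = 0.000936) and held with an estimated correlation (adjusted p = 0.033). Of 23 ectoderm regulators, 6 rose and none fell (7 over the list alone; median 0.57, adjusted p = 0.0013, and adjusted p = 0.232 with an estimated correlation), among them the neural gene sox-2 (2.94 ± 0.40), the Pax-6 gene vab-3 (3.18 ± 0.51) and the epidermal nuclear receptor gene nhr-25 (4.3-fold). The muscle regulator unc-120 (15.2-fold, 3.92 ± 0.64) and eya-1 (20.2-fold, 4.34 ± 0.71) were the 2 of 15 mesoderm and pharynx regulators that rose, 3 over the list alone. The endoderm regulators end-1 (-1.26 ± 0.80) and elt-2 (1.67 ± 0.70, not well above background at 2E) did not pass. Of 27 epidermis genes 7 rose and 2 fell (8 and 2 over the list alone; median 0.50, adjusted p = 0.00994, and adjusted p = 0.232 with an estimated correlation). Among these sym-1 rose by log2 10.70 ± 0.99 (7.15 in Cy5 alone), the cuticle collagen gene dpy-17 by 4.45 ± 0.87, the apical matrix gene noah-1 by 3.50 ± 0.64 (well above background in 2 of 3 embryos at 8E; 4.60 without 8E replicate 1) and the cadherin gene hmr-1 by 2.53 ± 0.55. The cysteine protease gene cpl-1 (11.3-fold) and the intestinal actin gene act-5 (2.96-fold) were the 2 of 17 gut genes that rose. Of 25 muscle genes only the integrin gene pat-3 rose (2.46-fold), and of 22 neuron genes unc-5, unc-18 and unc-76 did (3.22, 1.45 and 3.17), 4 over the list alone with 1 lower.

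Over the same span some transcripts of the germ line and of the oocyte fell in wild-type embryos. Among 16 germ line and P granule genes 4 fell (5 over the list alone) and none rose. These were the P granule helicase gene glh-2 (-6.04 ± 1.02), pgl-1 (-3.93 ± 0.70), gld-3 (-3.19 ± 0.53) and pgl-3 (-2.94 ± 0.75), the last at -0.84 in Cy5 alone (adjusted p = 0.607). The list passed (median -1.39, adjusted p = 0.00107, and adjusted p = 0.232 with an estimated correlation). Of 39 maternal oocyte transcripts 8 fell and 3 rose (12 and 3 over the list alone; median -1.18, adjusted p = 0.0169, and adjusted p = 0.539 with an estimated correlation). The egg activation gene egg-3 (-5.08 ± 0.85) and mex-1 (-3.42 ± 0.74) fell, while the caveolin gene cav-1 (6.24 ± 1.24) and the kinase gene mbk-2 (3.22 ± 0.65) rose. In the cell cycle list 9 of 39 rose and 4 fell (12 and 6 over the list alone; median 0.70, adjusted p = 0.00994, and adjusted p = 0.378 with an estimated correlation). The cyclin-dependent kinase inhibitor gene cki-1 rose 20.6-fold (4.36 ± 0.54), the cytokinesis kinesin gene zen-4 11.6-fold (3.54 ± 0.45) and the kinetochore gene knl-2 12.4-fold (3.64 ± 0.51). The replication licensing gene cdc-6 fell by 3.20 ± 0.34, and less in Cy5 alone, with log2 levels of 9.86 to 11.3 at 2E and 7.78 to 9.72 at 8E. In Cy5 alone that list did not pass (0.28, adjusted p = 0.727), and its direction turned with median centring and in the value table, so it is not settled. The medians of maternal transcripts (-2.32, adjusted p = 0.000383, and adjusted p = 0.375 with an estimated correlation), germ line genes (-2.32, adjusted p = 3.44e-05, and adjusted p = 0.201 with an estimated correlation) and ectoderm regulators (1.12, adjusted p = 0.000599, and adjusted p = 0.201 with an estimated correlation) lay farther from 0 in Cy5 alone. Ribosomal protein genes rose in 42 of 75 cases, 57 over the list alone (median 3.74 and 1.35 in Cy5 alone, adjusted p = 1.82e-23, and adjusted p = 0.314 with an estimated correlation), with rpl-3 (4.77 ± 0.70) and rps-4 (4.62 ± 0.91) among them; the reference channel moved the other way (-1.70). Chromatin regulators utx-1 (3.04 ± 0.76), a histone demethylase gene, and sop-2 (1.29 ± 0.33) rose, and 5 of 18 did over the list alone. Of 1548 X-linked genes 137 rose and 64 fell, also over the list alone. The Notch ligand gene apx-1 fell by 1.66 ± 0.42 and hsp-3 rose by 6.41 ± 0.86. The lists of gut, muscle, pharynx and neuron genes, of endoderm, mesoderm, Notch and chromatin regulators, of heat shock, of X-linked genes and of the mother's intestine and sperm did not pass. For gut, pharynx, heat shock and X-linked genes the median was below 0 and the mean above.

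In total 1610 of 12236 genes were called between 2E and 8E in wild type, 888 higher and 722 lower, and Cy5 alone called 1653 (978 higher, 675 lower), 960 in both. An unadjusted p under 0.05 was found for 3195 genes against 611.8 by chance, and the groups did not overlap for 22.5% of genes against 10% by chance. Outside the lists the largest rises were epi-1 (725-fold in the log ratio; log2 5.14 in Cy5 alone, adjusted p = 0.00155), the saposin gene spp-10 (8.98 ± 1.70, and 4.07 in Cy5 alone), acdh-1 (8.45 ± 0.88), the linker histone gene his-24 (8.02 ± 1.38, and 4.34 in Cy5 alone), fkb-5 (7.81), txdc-12.1 (7.79) and T09B4.5 (7.22). The largest falls were C01G8.1 (-5.81 ± 1.27), the phospholipase gene ipla-3 (-5.72 ± 0.57), enri-2 (-5.69), R12C12.5 (-5.65), EEED8.3 (-5.59), trcs-1 (-5.47), smim-14 (-5.37) and lsy-27 (-5.22). The reference channel carried over 50% of the log ratio for 26% of the called genes. Only 1 slide held both stages, with 1 embryo of each, 2E replicate 1 and 8E replicate 2, whose reference was weak. With slide as a block the comparison rests on that pair, so the 1841 genes called there (841 higher, 1000 lower, 864 as before) describe 1 embryo against 1. Within the pair the median was 1.37 for Hox genes, 0.60 for epidermis genes, 1.11 for ectoderm regulators, -2.47 for maternal transcripts, -3.40 for germ line genes, 1.95 for cell cycle genes and 7.17 for ribosomal protein genes. The split became 1405 higher and 358 lower with median centring (median of all genes 0.16), and 794 genes were called with scan day as a random block and 723 without both arrays of weak reference (475 higher, 248 lower). In a fit of the 6 compared arrays alone limma called none, with 1693 at an unadjusted p under 0.05.

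In mes-2 embryos the same span was measured on other arrays, all with a well-detected reference. Here nob-1 rose 20.7-fold (log2 4.37 ± 0.56, adjusted p = 0.000788) and the posterior Hox gene php-3 4.35-fold (2.12 ± 0.46), while lin-39 was at 0.42 ± 0.39. The neural gene cnd-1 rose at least 5.22-fold, sox-2 4.59-fold and unc-120 12.8-fold. The T-box genes tbx-38 (-2.39 ± 0.33) and tbx-37 (-1.27 ± 0.21), which act in the anterior pharynx, fell. The homeobox gene ceh-45 rose most (162-fold, 7.34 ± 1.43), then zip-8 (5.95 ± 1.16), R07E3.1 (4.90), T02E9.5 (4.82), C05D9.3 (4.73), sym-1 (22.5-fold, 4.49 ± 0.99) and ttr-52 (4.46), whose product marks dying cells for engulfment. The largest falls were ZK899.6 (-4.38 ± 1.16), vet-1 (-4.18 ± 1.13), Y52B11A.8 (-4.01), F40G9.9 (-3.98), the synaptonemal complex gene syp-6 (-3.89), F07A11.1 (-3.86), F57F4.2 (-3.79) and aptf-4 (-3.75). Ectoderm regulators rose in 5 of 23 cases with none lower, 9 over the list alone (median 0.80, adjusted p = 0.000159, and adjusted p = 0.11 with an estimated correlation), and Hox genes in 2 of 6, also over the list alone (median 0.35, mean 1.21, adjusted p = 0.0138, and adjusted p = 0.11 with an estimated correlation). Germ line genes (median -1.07, adjusted p = 0.0176) and transcripts of the mother's intestine and sperm (-1.01, 0.0138) lay lower with no member called, and came to adjusted p = 0.414 and 0.735 with an estimated correlation. Ribosomal protein genes lay slightly higher (0.66, adjusted p = 0.0138, and adjusted p = 0.816 with an estimated correlation), although rps-24 fell by 3.02 ± 0.80. Of 1548 X-linked genes 69 rose and 31 fell (78 and 38 over the list alone; median 0.06, adjusted p = 0.0176, and adjusted p = 0.26 with an estimated correlation). Gut genes ftn-1 (1.34 ± 0.27) and cpr-6 (1.39 ± 0.32), the epidermal gene lpr-3 (1.53 ± 0.40) and the pharynx gene tnt-4 (at least 1.51-fold) rose, and rnr-2 (-2.48 ± 0.59) and mec-4 (-1.01 ± 0.26) fell, in lists that did not pass. Over the list alone 4 of 15 mesoderm and pharynx regulators, 3 of 27 epidermis genes and 1 of 5 endoderm regulators rose, and 2 mesoderm regulators, 2 of 11 Notch genes and 1 epidermis gene fell. Median, mean and test differed in sign for mesoderm regulators, muscle, pharynx and cell cycle genes.

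Altogether 586 genes were called in mes-2, 268 higher and 318 lower, with 2231 at an unadjusted p under 0.05. The groups did not overlap for 33.9% of genes against 10% by chance, and Cy5 alone called 337 genes (152 higher, 185 lower). Embryos of the same number shared a slide, and with slide as a block 457 genes were called (146 higher, 311 lower), 276 of them as before. Within the 3 slides nob-1 differed by 4.29, 4.41 and 4.41, the Hox median was 0.77, 0.68 and 0.27 and the ectoderm median 1.03, 0.43 and 0.88. The lists that passed also did so with slide as a block, as did maternal oocyte transcripts with no member called (median -0.60, adjusted p = 0.00801, against adjusted p = 0.106 without the block, and adjusted p = 0.752 with an estimated correlation and no block). The 2 stages were scanned on separate days, and with scan day as a random block 13 genes were called. A fit of these arrays alone called 1404 genes, and 378 were called without 2E replicate 1, 355 without 8E replicate 2 and 405 without 8E replicate 3 (229 higher, 176 lower). The split was 164 higher and 50 lower with processed signals, 279 and 213 with median centring and 649 and 274 with the value table (median of all genes 0.12). The groups compared here and in wild type shared no array, but both comparisons took each gene's spread from all 18 arrays. Genes of low spread can thus be called in both, so the counts for independent lists may be too low. Of the genes higher at 8E, 84 were called in both genotypes against 19.4 for independent lists, and of the lower genes 71 against 18.8. Fold changes of all genes correlated across genotypes (r = 0.453; genes are not independent). Genes called higher in wild type had a median of 2.78 there and of 0.65 in mes-2, those called lower -2.41 and -0.67. The reverse held for genes called in mes-2, whose medians were 2.07 and -2.23 there and 0.53 and -0.62 in wild type.

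**Figure D1:**
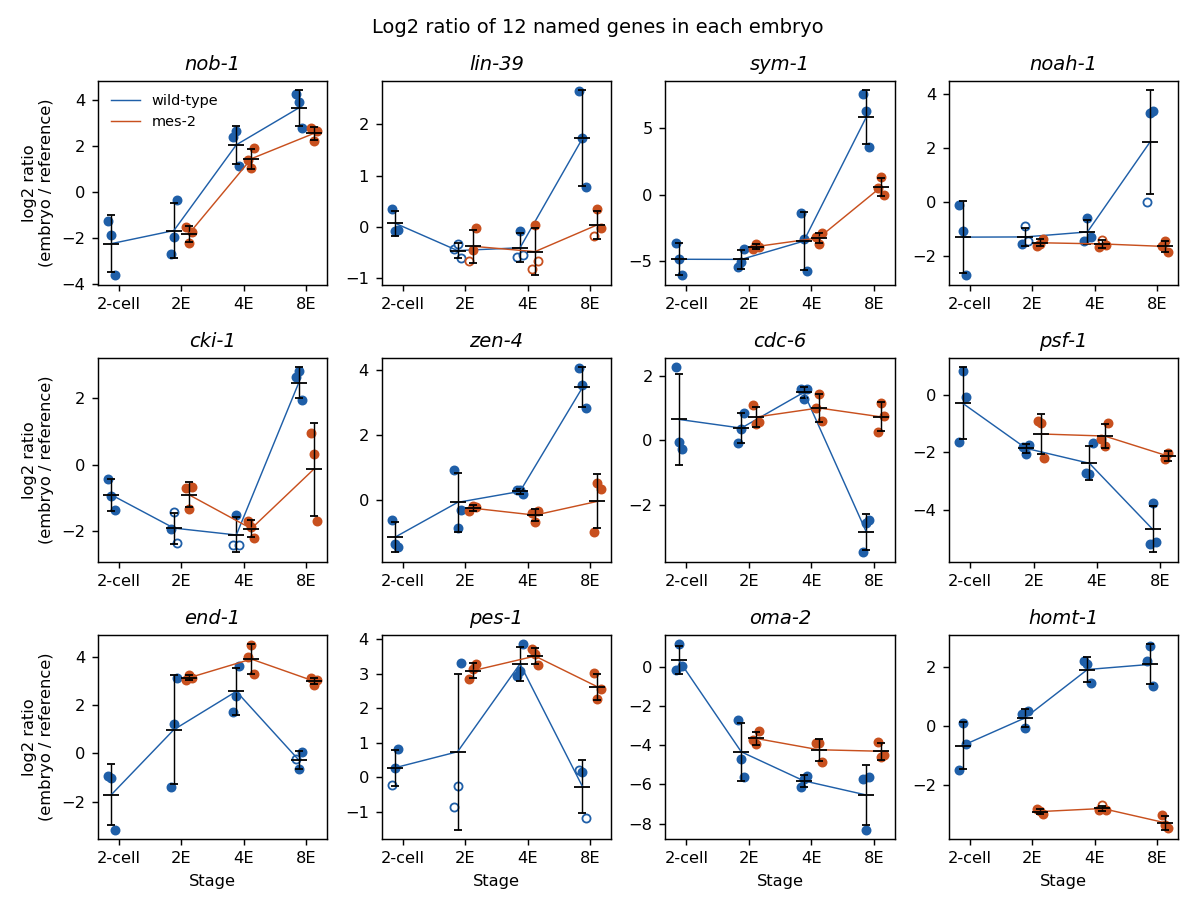
Log2 ratio of embryo over wild-type reference for 12 genes, chosen after their values were seen, against stage; points are single embryos, bars the mean and SD of 3 embryos, lines join the means of a genotype, and open circles mark values not well above background. Between 2E and 8E nob-1 rose by 5.34 in wild type and 4.37 in mes-2, and sym-1 by 10.70 and 4.49.

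At 2E most of the genes called between mes-2 and wild type were higher in the mutant (163 of 193). The cuticle collagen gene col-8 was at least 22.2-fold higher (adjusted p = 0.000352), the cathepsin B-like gene cpr-8 at least 30-fold (adjusted p = 0.0136), the X-linked gene C30F2.2 at least 15.6-fold (adjusted p = 0.00463) and K04H8.3 at least 40.8-fold (adjusted p = 0.0279; 0.065 in Cy5 alone). None of these 4 was well above background in a wild-type 2E embryo. The genes F07A11.1 (17.5-fold, log2 4.13 ± 0.56), C17B7.10 (14.9-fold, 3.89 ± 0.38, adjusted p = 9.72e-05) and col-154 (15.9-fold, 3.99 ± 0.82) were also higher, as was F58D5.7 (3.93 ± 0.78), which stood at 1.31 in Cy5 alone (adjusted p = 0.22). Lower in mes-2 were the coatomer gene copb-1 (-3.57 ± 0.65), homt-1 (-3.17 ± 0.31, adjusted p = 9.03e-05), F22E5.17 (-2.86 ± 0.31), T28A8.4 (-2.48), the flippase gene tat-1 (-2.34), the SET-domain gene set-23 (-2.27), the Patched-family gene ptc-3 (-2.04) and mat-3 (-2.02 ± 0.39, and -0.94 in Cy5 alone, adjusted p = 0.132), which encodes a part of the anaphase-promoting complex. Touch receptor neuron genes mec-4 (at least 1.74-fold) and mec-7 (2.14 ± 0.49, and 0.52 in Cy5 alone) were the 2 of 22 neuron genes that were higher, 3 over the list alone. The gut gene erm-1 was lower (-1.17 ± 0.26, adjusted p = 0.0375), 1 of 17, or 3 over the list alone.

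Of 1548 X-linked genes 25 were higher at 2E and none lower, also over the list alone (median 0.18, adjusted p = 0.0412, and adjusted p = 0.835 with an estimated correlation), while Cy5 alone had 20 higher and 9 lower (adjusted p = 0.109 for the list). Ribosomal protein genes lay above wild type in 75 of 75 cases with none called (median 2.15, adjusted p = 3.77e-15, and adjusted p = 0.835 with an estimated correlation). Within shared scan days the ribosomal median of wild-type 4E over 2E was 0.67 with 2E replicate 2 and -0.08 with 2E replicate 3. Against wild-type 2E replicate 1, which these days did not hold, 8E replicate 2, of weak reference, lay 7.17 higher on a shared slide. The ribosomal difference between genotypes may thus rest in part on wild-type 2E replicate 1. Transcripts of the mother's intestine and sperm lay above wild type in 29 of 31 cases, 11 of them called over the list alone (median 2.00, adjusted p = 6.96e-08, and adjusted p = 0.835 with an estimated correlation). Within that list the 22 major sperm protein probes, many matching several of these genes, had a median of 2.49 in Cy5 and the yolk protein genes of 0.54. Maternal oocyte transcripts lay lower (-0.58, adjusted p = 0.0453, and adjusted p = 0.835 with an estimated correlation) with none called and 1 over the list alone, and did not pass in Cy5 alone (adjusted p = 0.0693). No other list passed. Median, mean and test differed in sign for endoderm, ectoderm, Notch, Hox and chromatin regulators and for muscle, neuron and heat shock genes. Over the list alone, 2 mesoderm regulators, 1 Notch gene and 1 pharynx gene were higher and 1 mesoderm regulator and 1 Notch gene lower. In all 193 genes were called, 163 higher and 30 lower in mes-2. An unadjusted p under 0.05 was found for 2533 (611.8 by chance), and the groups did not overlap for 28.7% of genes against 10% by chance. Cy5 alone called 280 (156 higher, 124 lower), 95 in both. The split was 50 and 19 with processed signals, 26 and 1 with scale normalization and 1021 and 146 with the value table, which put the median of all genes at 0.17. Genotypes shared no scan day, and 21 genes were called with scan day as a random block, 20 in a fit of these arrays alone and 34 with array weights. The count was 79 without wild-type 2E replicate 1 and, without wild-type 2E replicate 3, 1348 (696 higher and 652 lower).

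At 4E mes-2 and wild-type embryos differed at few genes. The putative methyltransferase gene homt-1 was 26.2-fold lower in mes-2 (log2 -4.71 ± 0.31, adjusted p = 4.27e-06), and mut-16, a scaffold of small RNA amplification, was 14.2-fold lower (-3.83 ± 0.45, adjusted p = 0.00275). These were the 2 lower genes. Among 11 higher genes were the long noncoding RNA gene lep-5 (11.3-fold, 3.50 ± 0.59), soc-1 (at least 18.1-fold), the F-box genes fbxa-149 (11-fold, 3.46 ± 0.52) and fbxa-153 (7.78-fold, 2.96 ± 0.42), F22E5.7 (10-fold, 3.32 ± 0.43, adjusted p = 0.00598), npr-37 (at least 9.31-fold), F57B7.2 (2.83 ± 0.44) and gda-2 (2.60 ± 0.43). W04A8.1 (-1.95 ± 0.39, adjusted p = 0.0969), atad-3 (-1.35, 0.137) and ikke-1 (-3.70, 0.15) did not pass. Transcripts of the mother's intestine and sperm lay above wild type in 28 of 31 cases (median 1.60, adjusted p = 5.07e-06, and adjusted p = 0.679 with an estimated correlation) and ribosomal protein genes in 72 of 75 (1.00, adjusted p = 5.07e-06, and adjusted p = 0.841 with an estimated correlation), none of them called. Of 39 cell cycle genes 8 lay above 0 (median -0.73, adjusted p = 4.54e-05, and adjusted p = 0.42 with an estimated correlation), also with none called. Of 1548 X-linked genes 1 was called, higher, and 1029 lay above 0 (0.17, adjusted p = 0.000306, and adjusted p = 0.132 with an estimated correlation; none over the list alone). No other list passed. Median, mean and test differed in sign for endoderm and mesoderm regulators, muscle and neuron genes and maternal transcripts. The major sperm protein genes had a median of 2.09 in Cy5 and the yolk protein genes of 0.32. In total 13 genes were called by limma and 920 had an unadjusted p under 0.05 (611.75 by chance). Groups did not overlap for 19.1% of genes against 10% by chance, and Cy5 alone called 44, with 11 in both. The split was 3 higher and 2 lower with median centring, and 61 and 2 with the value table. With scan day as a random block 2 genes were called, in a fit of these arrays alone 1, with array weights 338 and with scale normalization none (821 unadjusted). The count was 8 (4 higher, 4 lower), 6 (3 and 3) and 5 (3 and 2) without wild-type 4E replicates 1, 2 and 3 in turn, 72 without mes-2 4E replicate 2 and 25 without mes-2 4E replicate 3.

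By 8E the genotypes differed at 2017 genes, 835 higher and 1182 lower in mes-2. The largest differences included manf-1, which was 81.1-fold lower (log2 -6.34 ± 0.83, adjusted p = 0.000268; -6.31 in Cy5 alone), the chaperone gene hsp-3, 129-fold (-7.01 ± 0.86, and -2.77 in Cy5 alone) and txdc-12.2, 64.9-fold (-6.02 ± 1.18). The chromodomain gene cec-5 (-6.22 ± 0.65, adjusted p = 7.84e-05), Y59A8B.8 (-6.43 ± 0.75), skp-1 (-6.11 ± 0.94), Y24D9A.6 (-5.98 ± 1.00) and epi-1 (-6.08 ± 1.22, and -1.99 in Cy5 alone, adjusted p = 0.157) were lower as well. Higher in mes-2 were F27C1.4 (116-fold, 6.86 ± 1.41), F15B10.3 (40.8-fold, 5.35 ± 1.09), pghm-1 (5.18 ± 0.93), which acts in peptide amidation, the sorting nexin gene snx-17 (5.16 ± 1.29), Y26E6A.3 (4.74), R04D3.4 (4.67) and nssp-15 (4.65). T23F2.4 was higher by 5.15 ± 1.22 in the log ratio and by 0.22 in Cy5 alone (adjusted p = 0.931).

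Of 27 epidermis genes 9 were lower in mes-2 at 8E and none higher, or 11 and 1 adjusted over the list alone (median -0.84, adjusted p = 0.0154, and adjusted p = 0.526 with an estimated correlation; -0.57 in Cy5 alone, adjusted p = 0.00143, and adjusted p = 0.16 with an estimated correlation). Among them were sym-1 (37.7-fold, -5.24 ± 0.99), hmr-1 (6.19-fold, -2.63 ± 0.55) and the protease inhibitor gene mlt-11 (-1.86 ± 0.32; well above background in 2 of 3 wild-type embryos). The gene noah-1 was 14.4-fold lower (-3.85 ± 0.64). It was not well above background in wild-type 8E replicate 1, without which the difference was -4.95. Regulators of cell fate went both ways. The Hox genes ceh-13 (-2.79 ± 0.58; -1.54 in Cy5 alone, adjusted p = 0.0946) and lin-39 (-1.69 ± 0.39; -3.54 in Cy5) were lower, php-3 was higher (1.77 ± 0.46) and nob-1 was at -1.11 ± 0.56 (adjusted p = 0.204). The endoderm gene end-1 was 9.67-fold higher (3.27 ± 0.80, adjusted p = 0.0124; 4.77 in Cy5), 1 of 5 members, which all lay above 0 (median 0.76, adjusted p = 0.232). The forkhead gene pes-1 was 7.43-fold higher (2.89 ± 0.78, adjusted p = 0.0206) and cnd-1 3.74-fold (1.90 ± 0.32; 0.88 in Cy5, adjusted p = 0.151), while vab-3 was lower (4-fold, adjusted p = 0.0156). In the Notch list aph-2, a part of gamma-secretase, was lower (-2.98 ± 0.49, adjusted p = 0.00114), lag-2 was at 2.62 ± 0.87 (adjusted p = 0.0536), and 2 genes were higher over the list alone. For tbx-38 (-1.61 ± 0.33) and apx-1 (1.60 ± 0.42) the direction turned in Cy5 alone (0.33 and -0.50), so it is not settled; tbx-38 was not well above background in wild type at 8E. Counts higher and lower, which stayed the same over the list alone, were 1 and 2 of 6 Hox genes, 2 and 1 of 23 ectoderm regulators and 1 and 1 of 15 mesoderm and pharynx regulators, and for 11 Notch genes they were 1 and 1 over all genes; none of these lists passed.

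Outside the epidermis, genes of differentiated tissues moved singly at 8E. Of 17 gut genes cpl-1 (-3.52 ± 0.55) and erm-1 (-0.83 ± 0.26) were lower and the ferritin gene ftn-1 at least 1.77-fold higher. Of 25 muscle genes pat-3 (-1.93 ± 0.34) and the myosin gene myo-3 (at least 3.04-fold lower; not passing in Cy5 alone, adjusted p = 0.204) were lower, of 7 pharynx genes tnt-4 was higher (at least 1.19-fold) and lat-1 lower (-1.98 ± 0.63), and of 22 neuron genes the exocytosis genes unc-18 (-1.57 ± 0.38) and unc-64 (-1.58 ± 0.51) were lower, 1 of them over the list alone. Among 39 maternal oocyte transcripts mbk-2 (-4.23 ± 0.65), par-3 (-2.06 ± 0.55) and par-6 (-0.81 ± 0.24) were lower and egg-3 (3.26 ± 0.85) and oma-2 (2.24 ± 0.72, adjusted p = 0.0475; named after its values were seen) higher, 1 higher and 3 lower over the list alone. The germ line genes gld-3 (2.21 ± 0.53) and glh-2 (3.77 ± 1.02; 1.77 in Cy5 alone, adjusted p = 0.364) were the 2 of 16 that were higher. Among 18 chromatin regulators sop-2 (-2.42 ± 0.33), the histone methyltransferase genes met-1 (-2.87 ± 0.57) and met-2 (at least 2.35-fold lower) and mig-32 (-2.61 ± 0.81, adjusted p = 0.527 in Cy5 alone; named after its values were seen) were lower and lin-61 (2.97 ± 0.66) higher, also over the list alone. In the cell cycle list 9 of 39 were lower and 3 higher, also over the list alone: zen-4 (-3.51 ± 0.45), the kinetochore gene knl-1 (-3.91 ± 0.62) and the retinoblastoma gene lin-35 (-3.49 ± 0.60) were lower and cdc-6 11.7-fold higher (3.55 ± 0.34, adjusted p = 5.1e-05). That list did not pass (median -0.39, adjusted p = 0.232; 0.39 in Cy5 alone). Of 1548 X-linked genes 147 were higher and 102 lower, 145 and 99 over the list alone (median 0.21, adjusted p = 0.0921). Of 12 heat shock genes hsp-3 alone was called (median 0.31, mean -0.11). The median and mean or test also differed in sign for mesoderm and ectoderm regulators and for gut genes.

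Transcripts of the mother's intestine and sperm lay higher in mes-2 at 8E in 28 of 31 cases (median 2.12, adjusted p = 0.00635, and adjusted p = 0.764 with an estimated correlation), with 1 member called lower. The major sperm protein genes had a median of 2.51 in Cy5 and the yolk protein genes of -0.103. Ribosomal protein genes lay lower in the log ratio (median -0.84, adjusted p = 0.232), with rps-2 (-1.79 ± 0.49) lower and rps-10 (2.37 ± 0.68; 0.31 in Cy5) higher and none called over the list alone, but higher in Cy5 alone (1.39, adjusted p = 8.62e-06, and adjusted p = 0.651 with an estimated correlation), so their direction is not settled. An unadjusted p under 0.05 was found for 3637 genes (611.8 by chance), and the groups did not overlap for 38.7% of genes against 10% by chance. Cy5 alone called 1892 genes (859 higher, 1033 lower), 1052 in both. Over 50% of the log ratio came from the reference channel for 26% of the called genes, and without both wild-type 8E arrays of weak reference 968 genes were called, 269 higher and 699 lower. The value table gave 2707 higher and 673 lower (median of all genes 0.37, and 0.18 with processed signals). With scan day as a random block 486 genes were called (130 higher, 356 lower).

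**Figure D2:**
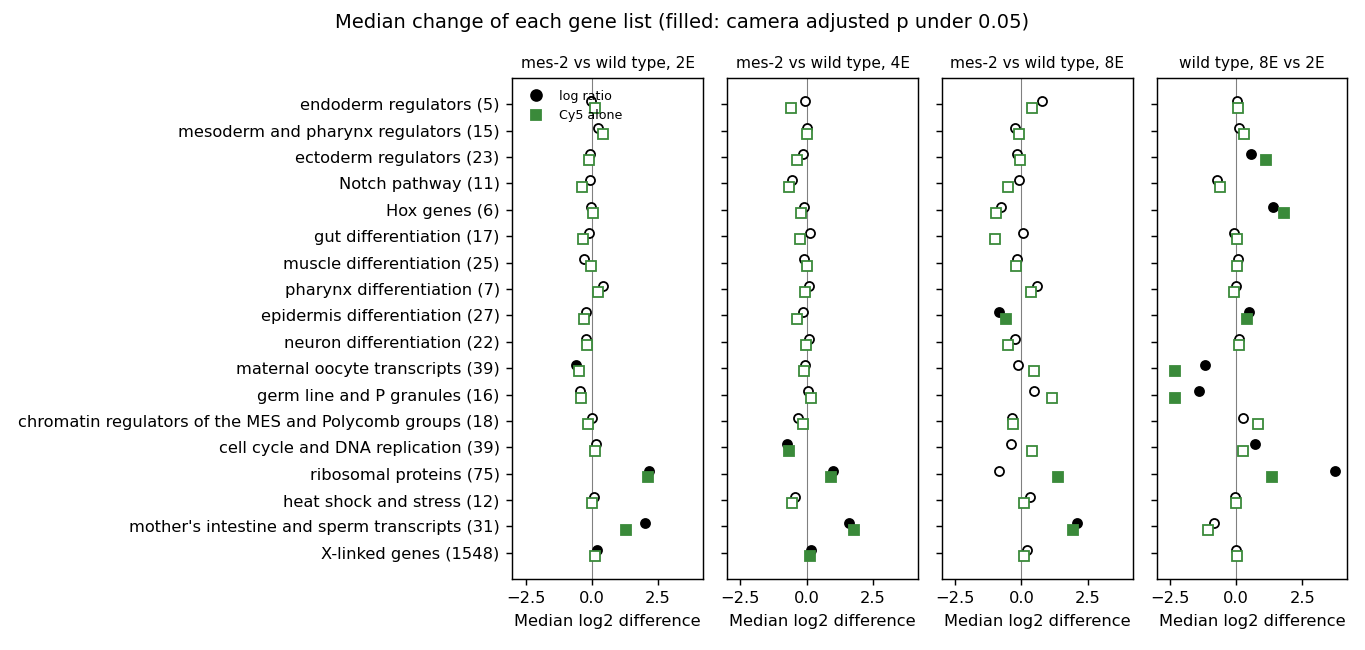
Median log2 difference of the 18 gene lists in 4 comparisons, with circles for the log ratio, squares for Cy5 alone, filled symbols for an adjusted p under 0.05 with the preset correlation, and the number of genes in brackets. In the log ratio the Hox median was 1.40 between wild-type 2E and 8E and the epidermis median -0.84 between mes-2 and wild type at 8E; the ribosomal median at 8E was -0.84 in the log ratio and 1.39 in Cy5 alone.

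The stage index placed embryos on the axis of genes that differed between wild-type 2E and 8E. It does not follow age at its low end, since the 2-cell embryos lay at 0.201 to 0.308 and the mes-2 2E embryos at 0.0299 to 0.0522 on such an axis, built in Cy5 without 2E replicate 1. Wild-type embryos lay at 0.255 ± 0.107 (SD, n = 3) at 2E, 0.310 ± 0.0736 at 4E and 0.838 ± 0.295 at 8E, where replicate 3 lay at 0.497 and the others at 1.01 and 1.00. The mes-2 embryos lay at 0.110 ± 0.0182, 0.269 ± 0.0441 and 0.395 ± 0.0149. All mes-2 embryos lay below all wild-type embryos at 2E (difference -0.145, exact permutation p = 0.1) and at 8E (-0.443, exact permutation p = 0.1, the smallest that 3 against 3 embryos allow), but not at 4E (-0.0406, exact permutation p = 0.5). Adjusted over the 3 stages these were 0.15, 0.15 and 0.5. At 2E and 8E the wild-type embryos were scored on 1 left-out axis each and the mes-2 embryos on the mean of these axes. The p-values there thus compare unlike scores. On the Cy5 axis built without wild-type 2E replicate 1, the mes-2 2E embryos lay between wild-type 2E replicates 2 and 3 (-0.0829 and 0.0829), which set its zero. Replicate 1 lay at 0.441 on it, so the order at 2E depends on the scoring. In Cy5 alone wild-type embryos lay at 0.30 ± 0.169, 0.318 ± 0.0893 and 0.826 ± 0.0142 and mes-2 embryos at 0.0667 ± 0.0181, 0.258 ± 0.0646 and 0.416 ± 0.0215. The differences were -0.233, -0.0602 and -0.410 (exact permutation p = 0.1, 0.3 and 0.1). Wild-type 2E replicate 1 lay highest of its group in Cy5 (0.445, against 0.114 and 0.340). The axis held 1091 to 2008 genes, and 1326 to 2299 in Cy5 alone. Without wild-type 8E replicate 1 or 2 the difference at 8E was -0.227 or -0.229.

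**Figure D3:**
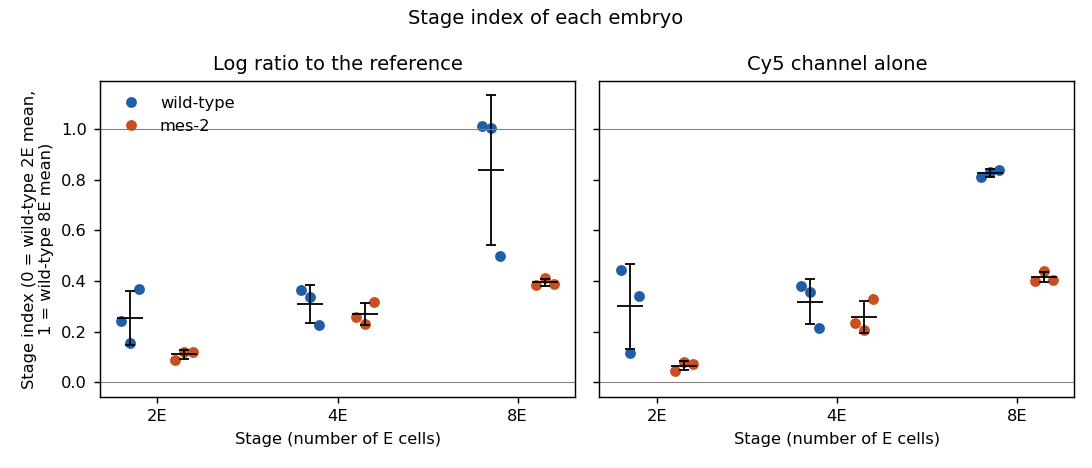
Stage index of each embryo (0, wild-type 2E mean; 1, wild-type 8E mean; no unit) from log ratios and from Cy5 alone, with points for embryos and bars for the mean and SD of 3 embryos. At 8E the mes-2 embryos sit near 0.395 in log ratios and 0.416 in Cy5, below all wild-type embryos. In log ratios the wild-type 8E embryos at 1.01 and 1.00 are those of weak reference, and the remaining one lies at 0.497.

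Whether the change from 2E to 8E itself differed between the genotypes was tested as an interaction. The change was smaller or opposite in mes-2 for sym-1 (log2 -6.20 ± 1.40, adjusted p = 0.0423), epi-1 (-7.32 ± 1.73), hsp-3 (-6.05 ± 1.22), manf-1 (-5.22 ± 1.18), fasn-1 (-5.11 ± 0.89), the calreticulin gene crt-1 (-5.18 ± 1.15), the collagen gene col-36 (-5.76 ± 0.98) and skr-21 (-5.14 ± 1.09). It was more positive in mes-2 for pdp-1 (4.44 ± 0.77), the pyrimidine synthesis gene umps-1 (4.44 ± 0.84), ipla-3 (4.19 ± 0.81), sfxn-1.5 (4.04), rop-1 (4.01), coel-1 (3.82), C13G5.2 (3.79) and R09F10.1 (3.76). In Cy5 alone 4 of these 16 genes passed, skr-21 (-5.39, adjusted p = 0.0442), rop-1 (4.53, 0.018), pdp-1 (4.16, 0.046) and ipla-3 (3.29, 0.0491). It gave -2.48 for sym-1 (adjusted p = 0.396) and -3.0 for epi-1 (adjusted p = 0.361). In all 207 genes were called, 69 more positive and 138 more negative in mes-2, with 1920 at an unadjusted p under 0.05 (611.8 by chance) and 153 in Cy5 alone (46 and 107), of which 72 were called in both. Ribosomal protein genes lay lower as a list, with none of 75 called over all genes or over the list alone (median -2.91, adjusted p = 9.77e-14, and adjusted p = 0.734 with an estimated correlation; -0.86 in Cy5 alone, adjusted p = 0.00835, and adjusted p = 0.766 with an estimated correlation), and in the reference channel they differed by 1.22. The ribosomal value may, as at 2E, rest in part on wild-type 2E replicate 1. Epidermis genes (-0.42, adjusted p = 0.217, with 4 lower over the list alone), Hox genes (-0.65, adjusted p = 0.395, with 2 lower) and all other lists did not pass. In Cy5 alone maternal oocyte transcripts (median 1.42, adjusted p = 0.0191, and adjusted p = 0.676 with an estimated correlation) and germ line genes (1.29, adjusted p = 0.0191, and adjusted p = 0.662 with an estimated correlation) were more positive in mes-2, against 0.89 (adjusted p = 0.448) and 0.84 (adjusted p = 0.296) in the log ratio. Of 1548 X-linked genes 15 were more positive and 24 more negative, 21 and 32 over the list alone. Median, mean and test differed in sign for X-linked and heat shock genes. The split was 52 and 56 with processed signals and 132 and 63 with the value table, and median centring put the median of all genes at -0.21. With scan day as a random block 1 gene was called, in a fit of the compared arrays alone 85, with array weights 444 and with slide as a block, where the wild-type change rests on 1 pair of embryos, 1166. Leaving out 1 array moved the count to 802 (wild-type 8E replicate 3), 353 (wild-type 2E replicate 3), 120 and 136 (wild-type 8E replicates 1 and 2), 79, 86 and 135 (mes-2 2E replicates 1, 2 and 3), 80 (mes-2 8E replicate 2) and 129 (mes-2 8E replicate 3; 63 and 66).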

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

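Of the tests in this part, those of the weak reference, of the 2-cell embryos on the axis from 2E to 8E and of carried-over maternal intestine, sperm and batch were chosen only after the results were seen.

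The change from 2E to 8E differed between mes-2 and wild type for 207 genes, by a test of the difference itself. The genes with the largest differences were pdp-1 (4.44), umps-1 (4.44), ipla-3 (4.19), sfxn-1.5 (4.04), rop-1 (4.01), coel-1 (3.82), C13G5.2 (3.79) and R09F10.1 (3.76), more positive in mes-2, and epi-1 (-7.32), sym-1 (-6.20), hsp-3 (-6.05), col-36 (-5.76), manf-1 (-5.22), crt-1 (-5.18), skr-21 (-5.14) and fasn-1 (-5.11), more negative. Ribosomal protein genes differed by a median of -2.91 with none of 75 called (adjusted p = 0.734 with an estimated correlation; -0.86 in Cy5 alone and 1.22 in the reference channel). Part of that ribosomal value may rest on wild-type 2E replicate 1. Of 100 splits of the 12 arrays drawn with a fixed seed, the real one included, 8 gave at least 207 genes. All 8 kept the genotypes apart at 8E and so still carry that difference. Their share therefore does not measure chance, which is not excluded for this count. The highest of the other splits gave 2578 genes. It swapped the genotypes at 8E alone, so that, apart from its sign, the value tested became the sum of the genotype differences at 2E and 8E.

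The reference channel, the same mix of wild-type embryos on every array, also differed between groups when tested alone. In Cy3, 2118 genes were called between mes-2 and wild type at 2E, 34 at 4E and 6871 at 8E, and across genes the changes in Cy5 correlated with those in Cy3 (r = 0.543, 0.39 and 0.369). Between wild-type 4E and 8E it was 5520 genes, between wild-type 2E and 8E 4940, between wild-type 2-cell and 2E 869, between mes-2 2E and 8E 8, and 26 for the difference in that change.

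The mes-2 8E embryos lay below all wild-type 8E embryos on the axis from wild-type 2E to 8E. A weak reference on wild-type 8E replicates 1 and 2 as the whole cause is argued against by Cy5 alone, which does not use the reference and gave a gap of -0.410 against a wild-type SD of 0.0142. A hybridisation or scan batch that moves both channels alike along this axis is argued against as well. On a Cy5 axis built from all wild-type 2E and 8E arrays, Cy3 differed by -0.0174 (wild-type SD 0.0546) and Cy5 by -0.601. That axis was chosen in Cy5 from arrays it scores, so its Cy5 gap is inflated and larger than the -0.410 above. What both channels share off this axis is not covered, as Cy3 alone called 6871 genes between these groups. Whether mes-2 8E embryos were at the state of wild-type 4E embryos stays open, with 152 genes called between these groups in Cy5 alone against 44 between the genotypes at 4E. A batch of embryo handling or amplification, which would act on Cy5 alone, cannot be told apart from genotype, and an effect of the mutation on the pace or the content of the programme may add to either.

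In Cy5, wild-type 2E replicates 1 and 3 both correlated more with the 2-cell embryos (mean r across genes 0.805 and 0.795) than with the other wild-type 2E embryos (0.665 and 0.741), but replicate 1 alone did so more than with the 4E embryos (0.698, against 0.915 for replicate 3). On an axis from 2-cell (0) to 4E (1) built without any 2E array it lay at 0.149, against 0.704 and 0.891 for replicates 2 and 3 and 0.634 to 0.720 for the mes-2 2E embryos. Its Cy5 stage index lay furthest towards 8E among wild-type 2E embryos (0.445, against 0.114 and 0.340); the 2-cell embryos had a mean of 0.258 on such an axis built without it, which decides nothing, as replicates 2 and 3 set its zero. A hybridisation or scan batch acting on both channels is argued against by Cy3, which differed on the axis from 2-cell to 4E by -0.00426 where Cy5 differed by -0.649. An embryo younger than its label and an amplification batch both stay open, as this array was the only one of its scan day.

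Major sperm protein genes lay higher in mes-2 embryos at all 3 stages, within a list of transcripts of the mother's intestine and sperm that came to adjusted p = 0.835, 0.679 and 0.764 with an estimated correlation and had no member called higher over all genes and 1 called lower at 8E. Carried-over maternal intestine is argued against by the yolk protein genes, abundant in that tissue, whose Cy5 medians were 0.54, 0.32 and -0.103 at 2E, 4E and 8E. Carried-over sperm as a whole would also raise gsp-4, nspd-3, spe-11, spe-15 and ssp-9. Their Cy5 medians were -0.214, -0.271 and -0.00844, while the major sperm protein probes had 2.49, 2.09 and 2.51. In Cy5 these 5 genes scattered from -2.03 to 1.27 at 2E, -0.816 to 0.386 at 4E and -3.08 to 0.714 at 8E. Their log-ratio medians were 0.526, 0.0880 and 0.145. The Cy5 medians go against carried-over sperm, but 5 scattered genes do not settle it. A batch acting on both channels stays open, with a Cy3 change of at most 0.271 times that of Cy5. A difference of the mes-2 mothers or embryos in this gene family may remain and was not tested.

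With 3 embryos in each group there are 10 splits, too few for a share under 0.05. The real split was the only 1 of 10 with as many genes for mes-2 against wild type at 2E (193; highest other 7), 4E (13; 10) and 8E (2017; 3). The same 1 of 10 was found for wild-type 8E against 4E (1022; 1), wild-type 8E against 2E (1610; 437), mes-2 8E against 2E (586; 5) and wild-type 2E against 2-cell (331; 208). For wild-type 4E against 2E, 6 of 10 splits had at least 1 gene (highest other 13). Of lists called, 6 of 10 splits had as many at 2E (4; highest other 5), 3 at 4E (4; 4), 7 at 8E (2; 4) and 2 between wild-type 2E and 8E (7; 9).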

How the results depend on the processing

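Scale normalization, the fit without both arrays of weak reference, and batch blocks in the list tests of wild-type 4E against 2E and mes-2 8E against 2E were chosen after the data had been seen. The alternatives gave 4666 values for 215 called pairs of a gene and a comparison. Of these values 3585 kept their direction and side of the threshold, 1078 kept their direction but did not pass and 3 reversed. Of 356 list values in the genotype comparisons and wild-type 8E against 2E these were 297, 57 and 2. Both tallies include quantile normalization of the mean intensity, which leaves log ratios as they are and so adds values that cannot change. Reversed were tbx-38 at 8E (0.33 in Cy5 alone, 0.58 in the value table), apx-1 at 8E (-0.50 in Cy5 alone) and the cell cycle list between wild-type 2E and 8E (where camera in limma gave 0.380 with median centring and 0.0456 in the value table). Outside that tally the ribosomal list between wild-type 4E and 8E also turned, to a median of -0.48 in Cy5 alone. The cause was not tested, here or for the counts that follow.

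Counts are given for mes-2 against wild type at 2E, 4E and 8E, then wild-type 4E against 2E, 8E against 4E and 8E against 2E, mes-2 8E against 2E, the difference of both changes, and wild-type 2E against 2-cell, where they moved over 1.5 times. Processed signals gave 69 at 2E and then 4, 1545, 2455, 214, 108 and 174. Median centring gave 5 at 4E, 0 for wild-type 4E and 218 for 2-cell. Cy5 alone gave 44 at 4E, 11 for wild-type 4E, 337 for mes-2 8E and 561 for 2-cell. No filter on dim probes gave 2 for wild-type 4E and 183 for 2-cell, and the stricter filter 2 for wild-type 4E. The value table gave 1167, 63, 3380, 12, 923 for mes-2 8E and 3085 for 2-cell. Scale normalization gave 27 at 2E, 0 at 4E, 0 for wild-type 4E, then 2019, 2494, 73 and 57 for 2-cell, and a stage index difference of -0.669. Scan day as a random block gave 21, 2, 486, 4, 305, 794, 13, 1 and 97, and as a fixed block 2 for wild-type 4E. Slide as a block gave 1166 for the difference. Array weights gave 34, 338, 3238, 2, 2417, 1784 for mes-2 8E, 444 and 556. Fits of the compared arrays alone gave 20, 1, 1300, 0, 239, 0, 1404, 85 and 0. These have fewer arrays behind the spread, yet the counts moved both ways. The count rose from 586 to 1404 for mes-2 8E against 2E and fell from 1610 to 0 for wild-type 8E against 2E. Mean r of Cy5 within a group was 0.704 to 0.858 in wild-type 2E and 8E and 0.897 to 0.949 in mes-2. A spread shared by all groups can thus make standard errors too small where wild-type 2E or 8E is compared. The 2-cell array of the shared design alone gave 130 and a design term 143. Without both arrays of weak reference the counts were 968, 541 and 723 for the comparisons of wild-type 8E.

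Lists called fell from 4 to 2 at 2E with median centring, Cy5 alone, scale normalization, array weights and the compared arrays alone, rose from 4 to 7 at 4E with scale normalization, and fell to 1 at 8E with the compared arrays alone. With an estimated correlation they were 0, 0 and 0 at 2E, 4E and 8E and 1 between wild-type 2E and 8E. The replicate number as a block gave 8 genes at 4E, 0 for wild-type 4E against 2E and 122 for the difference. Over all groups embryos with the same number did not vary together (median r across genes of -0.0124 over 45 pairs, -0.358 to 0.186). In mes-2 2E and 8E, where a number also marks a shared slide, r was 0.146, 0.0946 and 0.154 for the same number and -0.126 to 0.0051 otherwise, so each embryo correlated best with its own number, as a hint from the data. One of these pairs lay under 0.1, and with the number as a block 508 genes were called there.

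Leaving out each array in turn gave 79 to 1348 genes at 2E, 5 to 72 at 4E and 1346 to 2294 at 8E, with 2 to 4, 4 to 4 and 2 to 3 lists. It gave 0 to 672 for wild-type 4E against 2E, 427 to 1498 for 8E against 4E, 1091 to 2008 for 8E against 2E (5 to 8 lists), 355 to 471 for mes-2, 79 to 802 for the difference and 108 to 964 for 2-cell. The stage index difference at 8E ranged from -0.467 to -0.227. Quantile normalization of the mean intensity between arrays leaves log ratios as they are and tests nothing, and lists were not run with a random block. Signal over background limits wild-type 8E most, where the reference was well above background at 19.4% and 24.7% of probes on 2 arrays.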

Other observations

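All tests in this part were chosen only after results were seen.

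Some transcripts that rose in wild type after the 2-cell stage fell in mes-2 between 2E and 8E. In wild type vet-1 rose by log2 4.59 between 2-cell and 2E, and in mes-2 it fell by 4.18 between 2E and 8E, as did ZK899.6 (4.62, then -4.38) and F40G9.9 (4.17, then -3.98). In wild type their change from 2E to 8E was -2.55 (adjusted p = 0.165), -2.52 (adjusted p = 0.185) and -3.13 (adjusted p = 0.0451). Of 169 genes that rose in wild type between 2-cell and 2E, 19 fell in mes-2 between 2E and 8E, against 4.39 for independent lists. In Cy5 alone it was also 19, against 2.99. The groups compared share no array, but both fits took each gene's spread from arrays they have in common. Genes of low spread can thus be called in both, so the counts for independent lists may be too low. The other pairings gave 1 gene higher in both (3.70 for independent lists), 1 lower then higher (3.46) and 6 lower in both (4.11). In Cy5 alone these were 1 (2.46), 0 (4.40) and 12 (5.35), so there the excess was not limited to the first pairing.

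The gene homt-1 on chromosome I was lower in mes-2 at every stage (-3.17 at 2E, -4.71 at 4E and -5.37 at 8E, adjusted p = 9.03e-05, 4.27e-06 and 7.44e-07). It rose in wild type between 2E and 8E (1.81, adjusted p = 0.00173), while in mes-2 the change was -0.38 (adjusted p = 0.591) and the difference of both changes was -2.19 (adjusted p = 0.0259). F07A11.1 was higher in mes-2 at 2E (4.13) and fell in mes-2 by 8E (-3.86), a change that differed from that of wild type (-4.25, adjusted p = 0.0213). The maternal meiosis genes memi-2 and memi-3, which fell early in wild type, were higher in mes-2 at 8E (1.88, adjusted p = 0.0365, and 1.75, adjusted p = 0.0272).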
